A study of Mus musculus with 36 samples.

How the data were processed

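RNA from mouse embryonic fibroblasts, uninfected or transduced with Gata4, Hand2, Mef2c and Tbx5, untreated or with 1% DMSO, was measured at days 2, 7 and 21. The 36 libraries were placed in 12 groups of 3 by their labels. Per the labels' protocols, the cells were embryonic fibroblasts of mice with an mCherry reporter driven by the Myh6 promoter, kept in a StemPro34-based medium with FGF2, FGF10 and VEGF, and RNA was taken with TRIzol and a Direct-zol kit and made into libraries with a TruSeq RNA kit. Reads were handled with Trimmomatic, FastQC and kallisto, per the submitters' processing notes. The genome build, the transcript annotation and the use of strand are not given in the sources used here, so no coordinates are printed.

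The authors deposited TPM values per Ensembl gene in 2 tables, 1 for each arm, per the file headers. Each column sums to 1000000 over all entries, which include ribosomal RNA, 7SL and 7SK, so a change in an abundant noncoding RNA moves all other values. Protein-coding genes held 50.6 to 65.2% of TPM per library, 7SL RNA 13.2 to 25.4% and mitochondrial messenger RNA 0.277 to 2.05%. Of 50698 entries per table, 97 name no gene and held 0.248 to 4.81% of TPM, and they were left out without rescaling. The 50601 gene entries gave 50509 symbols after 92 with a repeated symbol were summed, and 50377 gene IDs matched GENCODE M21 without version, which was used for gene types only. Of the symbols, 21752 were protein-coding. TPM keeps no read depth, so the counting error of low values is unknown. All 36 columns of values were used.

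Values were analysed as log2(TPM + 1), a scale that understates the change of low genes, for genes at 1 TPM or more in at least 3 libraries of a table. A model with 1 mean per group was fitted over the 18 libraries of each table with limma 3.58.1 in R 4.3.3, with a mean-variance trend and 12 residual degrees of freedom, and p-values were adjusted by Benjamini and Hochberg within each comparison. A gene was called at an adjusted p under 0.05. The comparisons were 1% DMSO against untreated in each arm at each day, day 21 against day 2 in untreated cells, the difference of the DMSO effect between days 21 and 2 in each arm, and its difference between arms at each day from 1 fit over all 36 libraries. Since the arms were deposited in separate tables, levels of the 2 arms were never tested against each other. All tests were two-sided. All genes, groups, gene lists and tests were fixed before the data were examined, except where the text says that something was chosen after its values were seen.

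Named genes followed a rule. The 4 factors and Myh6 were always named. For each DMSO comparison the 5 largest rises and 5 largest falls were taken among called genes with a mean of at least 5 TPM in 1 group, no overlap between the libraries of the groups and no predicted or clone-type symbol. For differences between arms and changes over time 3 of each were taken by the same filters. The overlap filter alone would be met by chance in 10% of genes with 3 libraries against 3. From each gene list the 2 members with the smallest adjusted p that rose and the 2 that fell were added. Of these, the text gives values for the ones that fit its groups. A gene named by rule in a time comparison is not reported here.

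The 37 gene lists cover cardiac and fibroblast programmes, stress and metabolism, signalling and markers of other cell types. They were tested with camera against all other genes, with a preset correlation of 0.01 and Benjamini and Hochberg adjustment over lists, and again with an estimated correlation. A list needed at least 3 members tested, and members were also adjusted over the list alone. Over the DMSO comparisons, the arm differences and the time comparisons, 137 list calls were made. With an estimated correlation 3 of them held, those of smooth muscle markers in uninfected cells at day 21, sarcomere genes in the arm difference of day 7 and NRF2 response genes over time in uninfected cells.

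Whether replicate numbers pair libraries was checked from the data, as the correlation of same-numbered libraries' deviations from their group means. In GHMT cells these were 0.19 to 0.34 at day 2 and 0.18 to 0.25 at day 7, all over 0.1, so the numbers were taken to pair the libraries there, and no label states a shared batch or day. Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 TPM, median ratio scaling, the replicate number as a block, fits on the groups of a comparison alone, no trend, and each library left out. The block sets the same replicate effect on all days of an arm, and pairing within a day was not modelled. Rescaling to protein-coding genes, leaving out 3 libraries that stood apart, and the fry test of the lists were added after the data were seen. Those libraries are GHMT DMSO replicate 3 of day 21, GHMT DMSO replicate 1 of day 7 and uninfected untreated replicate 1 of day 21, so a result in uninfected cells loses 1 library under this setting and a result in GHMT cells 2. GHMT DMSO replicate 1 of day 21, closest to an untreated library, was not among them, and the lists of that comparison were tested without it as a further alternative added after the data were seen.

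The fit was tested on simulated data with changed genes. In uninfected cells at day 21 it recovered 29 of 67 genes changed 1.5-fold, 46 of 67 changed 2-fold and 61 of 66 changed 4-fold, and in GHMT cells at day 21 it recovered 14, 32 and 56. Raising the cell cycle list 1.5-fold gave adjusted p = 0.00398 with 0 of the other lists called. Noise was drawn independently for each gene, so that run cannot show how often lists of correlated genes are called falsely. Figures were drawn with matplotlib 3.10.9 and tables read with pandas 2.3.3 in Python 3.11.15.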

Results

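RNA from mouse embryonic fibroblasts was sequenced in 36 libraries, which fall into 12 groups of 3. The fibroblasts came from a strain with an mCherry reporter under the promoter of Myh6, the alpha myosin heavy chain of heart muscle. They were left uninfected or transduced with Gata4, Hand2, Mef2c and Tbx5 (GHMT), transcription factors of heart development that are used to turn fibroblasts into cardiomyocyte-like cells. Each arm was kept untreated or with 1% dimethyl sulfoxide (DMSO), a polar solvent, and sampled at days 2, 7 and 21. Values were deposited as TPM, transcript abundances scaled to a fixed sum per library, with between 15785 and 18496 genes at 1 TPM or more in a library. TPM keeps no read depth, so the depth of each library is unknown and no counting intervals are given. Nothing in the labels says that the 3 replicates of a group were separate cultures, so p-values measure the spread between these samples, which may be technical.

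The transduced factors were measured first, since they check the labels. In untreated uninfected cells at day 2, Gata4 (ENSMUSG00000021944.15) stood at 1.73 ± 0.220 TPM (SD, n = 3), Hand2 (ENSMUSG00000038193.4) at 3.43 ± 0.349, Mef2c (ENSMUSG00000005583.16) at 15.1 ± 3.57 and Tbx5 (ENSMUSG00000018263.11) at 6.98 ± 1.17 TPM. In untreated GHMT cells of the same day the means were 111 ± 25.1, 106 ± 20.5, 895 ± 247 and 122 ± 10.2 TPM. The arms came in separate tables, so these levels stand side by side without a test, and whether transduced and resident transcripts share one entry is not given in the sources used here. In GHMT cells at day 7, Gata4 was higher with DMSO by 0.87 ± 0.23 (log2, SE), Hand2 by 0.90 ± 0.26, Mef2c by 0.88 ± 0.33 and Tbx5 by 0.98 ± 0.23, none past the unpaired test (adjusted p = 0.099, 0.13, 0.20 and 0.070). Their mean was higher in all 3 same-numbered pairs (0.81 to 0.99). At day 21 the differences were 0.73 ± 0.23, 0.78 ± 0.26, 0.78 ± 0.33 and 0.73 ± 0.23 (adjusted p = 0.076, 0.097, 0.16 and 0.078). At day 2 they were 0.21, 0.11, 0.07 and 0.16, each with adjusted p = 1.

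Myh6 (ENSMUSG00000040752.15), whose promoter drives the reporter, rose with DMSO in GHMT cells at days 7 and 21. At day 7 it stood at 319.7 ± 138 against 55.7 ± 26.3 TPM, a log2 change of 2.51 ± 0.35 with adjusted p = 0.010. At day 21 it stood at 971 ± 435 against 221 ± 25.2 TPM, a change of 2.04 ± 0.35 with adjusted p = 0.0058. At day 2 it stood at 1.31 ± 0.378 against 0.793 ± 0.304 TPM (adjusted p = 1), and no uninfected group had a mean above 0.324 TPM. The call at day 7 was lost without untreated replicate 3, where adjusted p was 0.052. Myh6 gave the only 2 calls among the factors and the reporter gene over the 6 DMSO comparisons, and none was called when each comparison was fitted on its 6 libraries alone. With libraries rescaled to their protein-coding total, an alternative added after the data were seen, Tbx5 at day 7 (adjusted p = 0.049) and Gata4 and Tbx5 at day 21 (adjusted p = 0.046 and 0.036) were called too. Of the factors, Tbx5 at day 7 was called without untreated replicate 1 (adjusted p = 0.039), and Gata4 and Hand2 at day 21 without DMSO replicate 1 (adjusted p = 0.034 and 0.029).

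**Figure D1:**
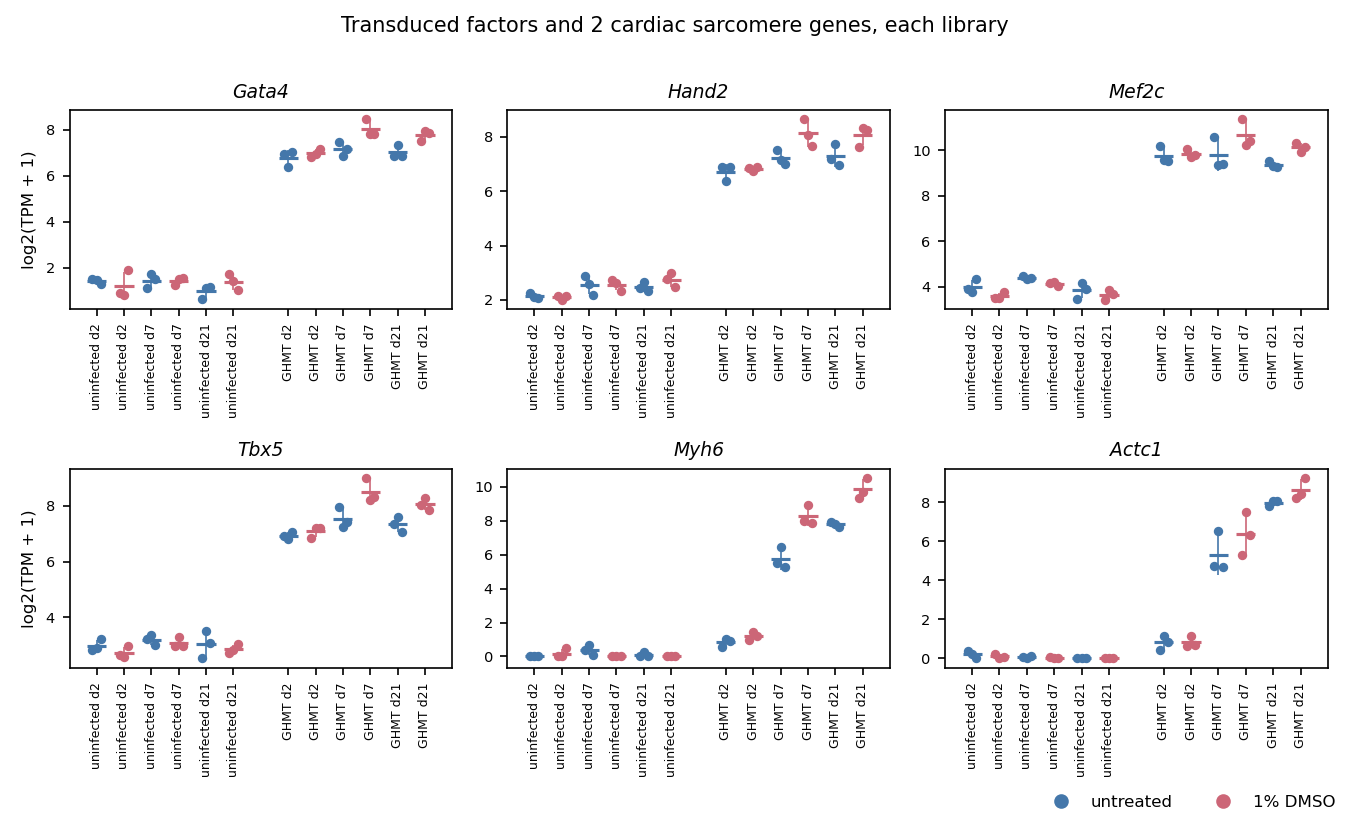
TPM on a log2(TPM + 1) scale of the 4 transduced factors, Myh6 and Actc1 in each library by arm and day, untreated in blue and 1% DMSO in red, where points are libraries, bars are means and lines are SDs. All GHMT libraries lie above all uninfected libraries for the 4 factors, and Myh6 with DMSO at day 7 averaged 319.7 TPM against 55.7 TPM untreated.

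The DMSO comparison in uninfected cells shows what the solvent changed in fibroblasts without the factors. At day 2 the metallothioneins Mt1 and Mt2, which bind metal ions, rose. Mt2 stood at 766 ± 94.6 against 339.5 ± 29.8 TPM (SD, n = 3), a log2 change of 1.17 ± 0.16 (SE) with adjusted p = 0.0076, and Mt1 at 1036 ± 68.8 against 489.6 ± 85.5 TPM, a change of 1.09 ± 0.13 with adjusted p = 0.0069. Lrp11, a member of the lipoprotein receptor-related family, rose by 1.15 ± 0.16 (adjusted p = 0.0076). Gap43, a protein of growing axons, fell from 18.2 to 5.62 TPM (−1.49 ± 0.19, adjusted p = 0.0076), Phyhd1 from 96.6 to 40.9 TPM (−1.25 ± 0.16), and the Wnt receptor partner Lgr5 from 8.19 to 2.10 TPM (−1.58 ± 0.22).

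Among the lists at day 2, all 30 cell cycle and mitosis genes were higher with DMSO (median 0.88, adjusted p = 1.3e-12, adjusted p = 0.38 with an estimated correlation), although none was called over all genes and 2 when adjusted over the list alone. Of 25 myofibroblast and TGF-beta response genes 18 were lower (median −0.46, adjusted p = 4.1e-06, adjusted p = 0.14 with an estimated correlation), with none called and 8 when adjusted over the list alone. Collagens and fibroblast matrix genes were lower in 28 of 32 (median −0.23, adjusted p = 5.2e-07, adjusted p = 0.41 with an estimated correlation), none called and 1 when adjusted over the list alone. Integrated stress response genes were lower in 19 of 23 (median −0.29, adjusted p = 5.2e-07, adjusted p = 0.17 with an estimated correlation), none called and 4 when adjusted over the list alone. In the smooth muscle list the regulatory myosin light chain Myl9 fell (−1.17 ± 0.20, adjusted p = 0.032), with 4 of 14 members when adjusted over the list alone (median −0.36, adjusted p = 9.1e-06, adjusted p = 0.12 with an estimated correlation). The metallothionein list had Mt1 and Mt2 as its 2 called members of 10, and 3 when adjusted over the list alone (median 0.33, adjusted p = 0.0018, adjusted p = 0.15 with an estimated correlation).

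By limma, 36 genes rose and 21 fell of 19979 tested at day 2, against 15 and 34 after median ratio scaling. The RNA 7SK took 5.03% of TPM with DMSO and 3.84% without. Without untreated replicate 1, 2 or 3 the count of 57 became 14, 29 or 10, and without DMSO replicate 1, 2 or 3 it became 10, 15 or 20. Fitted on these 6 libraries alone it was 2, and none of the 14 called genes named by rule was called. Mt1, Mt2, Lrp11, Gap43 and Phyhd1 held without any 1 library, while Lgr5 was lost without untreated replicate 3 or DMSO replicate 1 (highest adjusted p = 0.072) and Myl9 without any 1 of the 6 (highest adjusted p = 0.13). With the uninfected untreated replicate 1 of day 21, which stood apart, left out of the fit, the count was 119.

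At day 7 in uninfected cells, Comp, Myl9, Col28a1, Mfap4, Ltbp2 and Tpm2 were among the genes that fell with DMSO. Comp, a matrix protein of cartilage and tendon, went from 10.0 ± 1.66 to 2.48 ± 0.231 TPM (SD, n = 3), a log2 change of −1.66 ± 0.17 (SE) with adjusted p = 0.00044. Myl9 went from 17.2 ± 4.79 to 3.66 ± 0.325 TPM (−1.94 ± 0.20, adjusted p = 0.00044). Col28a1, a collagen (−3.18 ± 0.39), the microfibril protein Mfap4 (−2.54 ± 0.32), the latent TGF-beta binding protein Ltbp2 (−2.48 ± 0.35) and tropomyosin Tpm2 (−1.54 ± 0.24) fell with adjusted p between 0.0015 and 0.0082. Slc22a17, a lipocalin receptor, rose by 1.08 ± 0.15 (adjusted p = 0.0032) and Mt1 by 0.88 ± 0.13 (adjusted p = 0.0049).

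All 30 cell cycle and mitosis genes were again higher at day 7 (median 1.05, adjusted p = 3.3e-18, adjusted p = 0.46 with an estimated correlation), with the mitotic kinase Aurkb called (1.18 ± 0.28, adjusted p = 0.047) and 28 members when adjusted over the list alone. Of the 25 myofibroblast genes 7 fell, 10 when adjusted over the list alone (median −0.57, adjusted p = 1.2e-06, adjusted p = 0.099 with an estimated correlation). Of 32 collagen and matrix genes 2 fell, elastin Eln (−1.44 ± 0.31) and Col8a1 (−1.38 ± 0.31), and 6 when adjusted over the list alone (median −0.39, adjusted p = 1.2e-06, adjusted p = 0.59 with an estimated correlation). The smooth muscle list had 2 members that fell, Myl9 and Tpm2, and 4 when adjusted over the list alone (median −0.41, adjusted p = 2.2e-06, adjusted p = 0.085 with an estimated correlation). All 19 macrophage and leukocyte markers were lower, none called over all genes or when adjusted over the list alone (median −0.76, adjusted p = 1.2e-06, adjusted p = 0.53 with an estimated correlation). In the Wnt list Lgr5 (−1.65 ± 0.22) and the secreted inhibitor Sfrp2 (−2.24 ± 0.44) fell, 5 of 17 when adjusted over the list alone (median −0.34, adjusted p = 0.011, adjusted p = 0.48 with an estimated correlation). Of 19 matrix proteases 2 fell, Mmp3 (−2.20 ± 0.45) and Mmp23 (−1.0 ± 0.17), and 3 when adjusted over the list alone (median −0.27, adjusted p = 0.022, adjusted p = 0.61 with an estimated correlation).

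By limma, 129 genes rose and 208 fell at day 7 of 19979 tested, and 11 and 118 of them by more than 2-fold. After protein-coding rescaling 418 of 692 rose. The RNA 7SK took 4.34% of TPM with DMSO and 3.14% without. Without untreated replicate 1, 2 or 3 the count of 337 became 83, 81 or 129, and without DMSO replicate 1, 2 or 3 it became 87, 155 or 109. Comp, Myl9, Col28a1, Mfap4, Ltbp2, Tpm2, Slc22a17, Mt1, Lgr5, Grem1 and Cox6a2 held without any 1 library. Eln, Col8a1, Mmp3 and Aurkb were lost without any 1 of the 6, Sfrp2 unless untreated replicate 3 or DMSO replicate 2 was the one left out, and likewise Mmp23, with adjusted p up to 0.15. After median ratio scaling Aurkb had adjusted p = 0.064. With the uninfected untreated replicate 1 of day 21 left out of the fit, the count was 592.

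At day 21 in uninfected cells, Postn, Eln, Comp, Myl9, Mfap4 and Apoe were among the genes that fell with DMSO. Periostin, Postn, a matrix protein of activated fibroblasts, went from 713 ± 102 to 91.8 ± 26.6 TPM (SD, n = 3), a log2 change of −2.97 ± 0.24 (SE) with adjusted p = 1.7e-05. Elastin, Eln, went from 93.0 ± 17.1 to 12.8 ± 2.89 TPM (−2.78 ± 0.31, adjusted p = 0.00031), Comp from 24.8 ± 1.38 to 3.53 ± 0.630 TPM (−2.52 ± 0.17, adjusted p = 6.1e-06) and Myl9 from 21.5 ± 3.89 to 2.30 ± 0.677 TPM (−2.78 ± 0.20, adjusted p = 6.1e-06). Mfap4 fell by 3.78 ± 0.32 on the log2 scale and the lipoprotein Apoe by 3.12 ± 0.27, both with adjusted p = 1.8e-05. The largest rises by the naming rule were of Nxph1 (1.53 ± 0.31, adjusted p = 0.016), a neurexin-binding glycoprotein, and Upk1b (1.38 ± 0.31, adjusted p = 0.028), a urothelial and mesothelial membrane protein. Slmapos2 had 1.36 ± 0.23, but its symbol marks an antisense transcript and strand use in quantification was not stated, so it is uncertain.

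Of 32 collagen and matrix genes 31 were lower at day 21, 4 called and 11 when adjusted over the list alone (median −0.48, adjusted p = 1.1e-10, adjusted p = 0.30 with an estimated correlation). The smooth muscle list had 5 of 14 called, among them Myl9 and Tpm2 (−2.28 ± 0.24), and 8 when adjusted over the list alone. It was the only list of a DMSO comparison whose call held with an estimated correlation (median −0.71, adjusted p = 5.6e-09, adjusted p = 0.018 with an estimated correlation). Of 25 myofibroblast genes 7 fell and 10 when adjusted over the list alone (median −0.49, adjusted p = 1.5e-07, adjusted p = 0.061 with an estimated correlation). Of the matrix proteases 3 of 19 fell, including Mmp23 (−1.75 ± 0.17, adjusted p = 8.3e-05), and 5 when adjusted over the list alone (median −0.37, adjusted p = 3.1e-05, adjusted p = 0.30 with an estimated correlation). The 8 sarcomere genes measured were all lower, with Des called (−1.24 ± 0.23) and 2 when adjusted over the list alone (median −0.37, adjusted p = 0.0028, adjusted p = 0.061 with an estimated correlation). Cholesterol biosynthesis genes were higher in 22 of 24, none called and 1 when adjusted over the list alone (median 0.51, adjusted p = 9.7e-06, adjusted p = 0.53 with an estimated correlation).

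Chemokines Ccl8 (−2.59 ± 0.30) and Ccl11 (−2.79 ± 0.62) fell within an inflammatory list of 22 whose median was −0.05 and mean −0.40 (adjusted p = 0.041 and adjusted p = 0.58 with an estimated correlation), 3 when adjusted over the list alone. This call ended, and its test turned to the opposite direction, when untreated replicate 1 of this day was left out (adjusted p = 0.94). In the Wnt list Lgr5 (−1.59 ± 0.22), Sfrp2 (−2.38 ± 0.44) and 1 more of 17 fell, with 1 higher and 9 lower when adjusted over the list alone (median −0.73, adjusted p = 0.00013, adjusted p = 0.28 with an estimated correlation). The cell cycle inhibitor Cdkn1a went from 266 to 112 TPM (−1.24 ± 0.22, adjusted p = 0.0083), and all 30 cell cycle and mitosis genes were higher, none called (median 0.42, adjusted p = 3.1e-05, adjusted p = 0.61 with an estimated correlation). Among the untreated libraries, replicate 1 had the highest value of the list member Mki67. Markers of other cell types moved beside these groups. All 19 macrophage and leukocyte markers were lower (median −0.76, adjusted p = 9.6e-07, adjusted p = 0.39 with an estimated correlation). Of 15 epicardial and mesothelial markers 12 were higher, with Upk1b called and 7 when adjusted over the list alone (median 0.46, adjusted p = 0.00013, adjusted p = 0.39 with an estimated correlation). Mt1 rose by 0.83 ± 0.13 (adjusted p = 0.0030) and Mt2 by 0.72 ± 0.16 (adjusted p = 0.025).

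By limma, 145 genes rose and 327 fell at day 21 of 19979 tested, 18 and 166 of them by more than 2-fold, and after protein-coding rescaling 443 of 793 rose. The RNA 7SK took 4.15% of TPM with DMSO and 2.83% without. Untreated replicate 1 had a median correlation of 0.942 with its group and was closest to a DMSO library. Without it the count of 472 was 721, against 268 without untreated replicate 2 or 3, and 477, 229 or 224 without DMSO replicate 1, 2 or 3. Fitted on the 6 libraries alone the count was 46, and 10 of the 39 called genes named by rule were still called. Postn, Eln, Comp, Myl9, Mfap4, Apoe, Tpm2, Mmp23, Ccl8, Lgr5, Cdkn1a, Mt1 and Slmapos2 were among 19 named genes that held without any 1 library. Nxph1 was lost without DMSO replicate 2, Ccl11 without DMSO replicate 2 or 3, Des without untreated replicate 2 or DMSO replicate 3, and Sfrp2 without untreated replicate 2. Mt2 was lost unless untreated replicate 1 was left out, and Upk1b unless untreated replicate 3 or DMSO replicate 1 was, with adjusted p up to 0.12. After median ratio scaling Mt2 had adjusted p = 0.083.

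**Figure D2:**
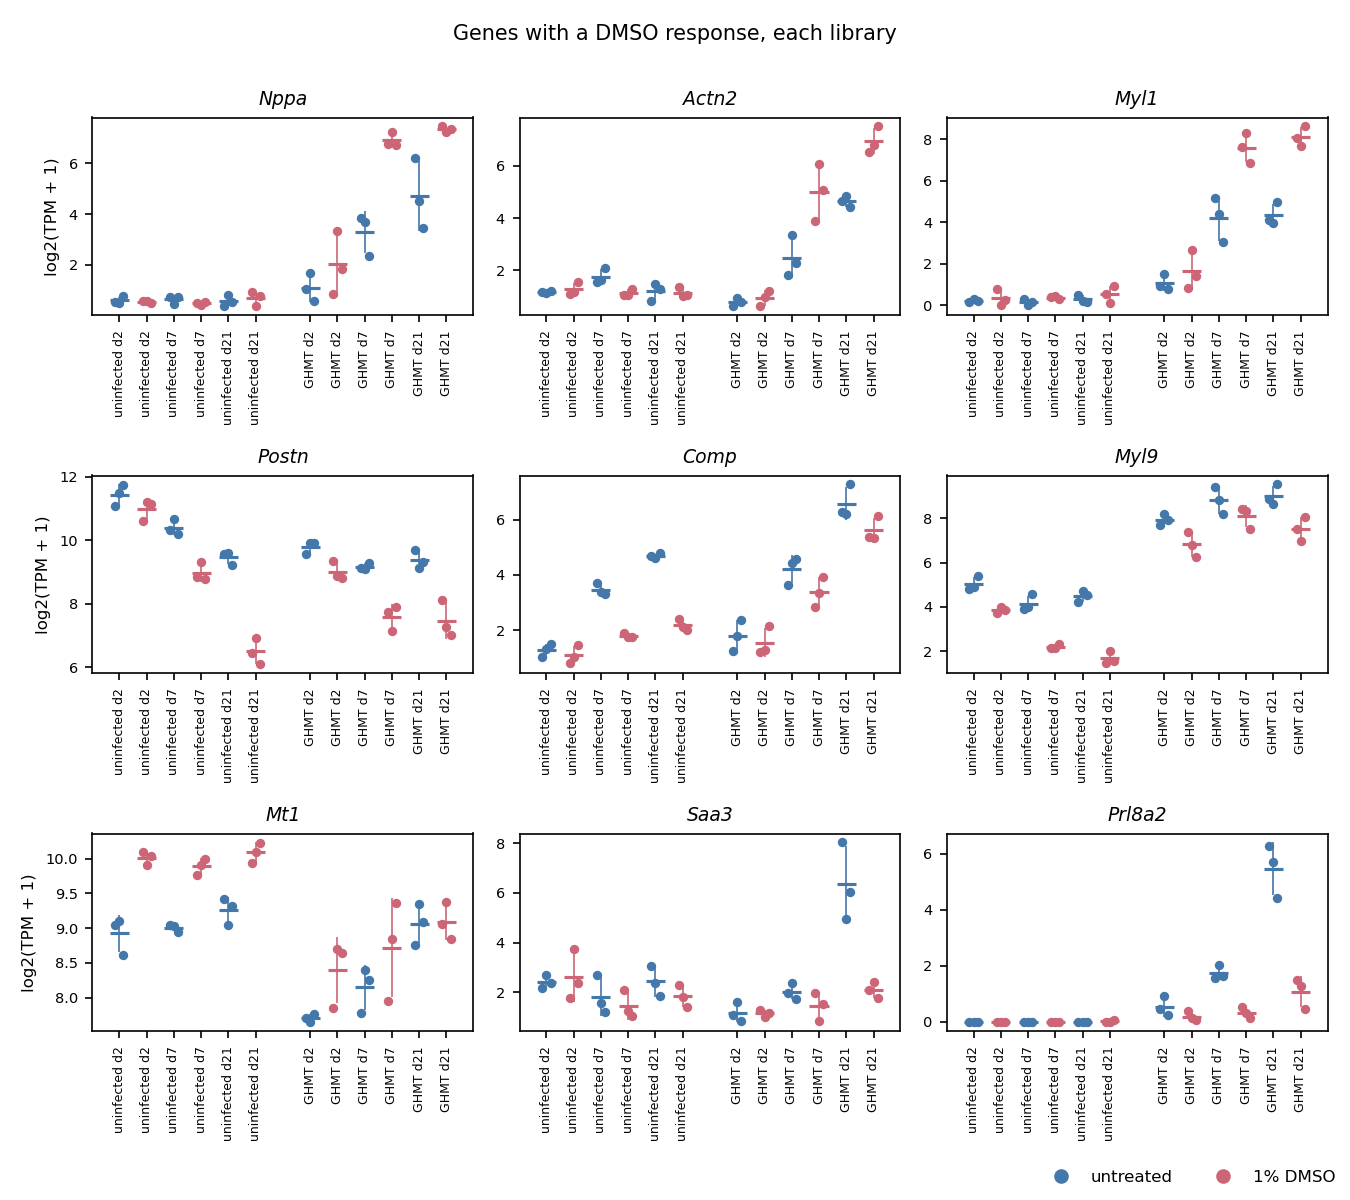
TPM on a log2(TPM + 1) scale of 9 genes in each library by arm and day, untreated in blue and 1% DMSO in red, where points are libraries, bars are means and lines are SDs. Postn at day 21 averaged 91.8 TPM with DMSO and 713 TPM without in uninfected cells, and 186 and 672 TPM in GHMT cells.

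The same comparison in GHMT cells asks what the solvent changed while fibroblasts received the cardiac factors. At day 2 limma called 1 gene of 20618, the predicted gene Gm26217, which lies outside the naming rule and was chosen after its values were seen (1.95 ± 0.14, adjusted p = 2.3e-05). With all libraries 706 genes had an unadjusted p under 0.05. Gm26217 was lost without any 1 of the 3 DMSO libraries, where 1 other gene, lower with DMSO, was called without replicate 1 and 0 without replicate 2 or 3. It was lost too in a fit on these 6 libraries alone, which called 5 other genes, and without untreated replicate 1 there were 2 calls. The sarcomere list had a median of −0.04 (adjusted p = 0.053). Smooth muscle markers were lower in 14 of 15 (median −0.41, adjusted p = 7.8e-08, adjusted p = 0.15 with an estimated correlation). Collagens and matrix genes were lower in 29 of 31 (median −0.25, adjusted p = 8.8e-07, adjusted p = 0.41 with an estimated correlation), in both lists with no member called over all genes or when adjusted over the list alone. Myofibroblast genes were lower in 17 of 25 (median −0.24, adjusted p = 0.00027, adjusted p = 0.55 with an estimated correlation). Matrix proteases were lower in 16 of 21 (median −0.17, adjusted p = 0.00027, adjusted p = 0.41 with an estimated correlation), likewise without a called member.

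At day 7 in GHMT cells, Nppa, Myl1, Actn2 and Myl4 were among the genes that rose with DMSO. Nppa, the gene of the atrial natriuretic peptide, went from 9.81 ± 4.98 to 122 ± 25.8 TPM (SD, n = 3), a log2 change of 3.63 ± 0.66 (SE) with adjusted p = 0.029. Myl1, a light chain of striated muscle myosin, went from 20.7 ± 13.9 to 209 ± 98.2 TPM (3.40 ± 0.55, adjusted p = 0.021). The Z-disc protein Actn2 went from 5.23 ± 3.58 to 37.4 ± 26.1 TPM (2.51 ± 0.46, adjusted p = 0.029) and Myl4, an atrial light chain, from 135 ± 49.6 to 492 ± 155 TPM (1.88 ± 0.40, adjusted p = 0.046). Postn fell from 577 ± 43 to 196 ± 49.3 TPM (−1.58 ± 0.26, adjusted p = 0.021). Plac8 (−3.23 ± 0.55), Fxyd1, a regulator of the sodium pump (−2.46 ± 0.35), and the water channel Aqp1 (−2.30 ± 0.49, adjusted p = 0.046) fell. Ly6c1 (−2.85 ± 0.48) and Ly6a (−2.27 ± 0.43) also had lower values, but they belong to a family of near-identical copies and are uncertain.

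Of 25 sarcomere genes 21 were higher at day 7, 4 of them called, Myh6, Actn2, Myl4 and 1 more, and 11 when adjusted over the list alone (median 0.83, adjusted p = 7.3e-07, adjusted p = 0.42 with an estimated correlation). Cardiac transcription factors, a list that holds the 4 transduced genes, were higher in 14 of 19 (median 0.32, adjusted p = 0.0067, adjusted p = 0.37 with an estimated correlation), with Prox1 called (0.81 ± 0.15) and 7 up and 1 down when adjusted over the list alone. Calcium handling genes had none called of 21 and 6 when adjusted over the list alone (median 0.28, adjusted p = 0.011, adjusted p = 0.65 with an estimated correlation). In the other direction, 31 of 32 interferon response genes were lower, none called (median −0.72, adjusted p = 6.0e-10, adjusted p = 0.42 with an estimated correlation). Inflammatory genes were lower in 20 of 25 (median −0.33, adjusted p = 0.0017, adjusted p = 0.42 with an estimated correlation). Collagens and matrix genes were lower in 23 of 31 (median −0.21, adjusted p = 0.0010, adjusted p = 0.42 with an estimated correlation). Ribosomal protein genes were lower in 28 of 32 (median −0.18, adjusted p = 7.3e-07, adjusted p = 0.42 with an estimated correlation), and none of these 3 lists had a called member over all genes or when adjusted over the list alone. Myofibroblast genes were lower in 15 of 25, with Postn called and 2 when adjusted over the list alone (median −0.37, adjusted p = 0.0029, adjusted p = 0.42 with an estimated correlation). Histone acetyltransferase and bromodomain genes were higher in 22 of 24, none called (median 0.29, adjusted p = 0.0010, adjusted p = 0.42 with an estimated correlation).

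By limma, 73 genes rose and 73 fell at day 7 of 20618 tested. Median ratio scaling moved all genes by 0.10 (log2), and relative to that shift Myl4 had adjusted p = 0.056. Without untreated replicate 1, 2 or 3 the count of 146 became 111, 11 or 12, and without DMSO replicate 1, 2 or 3 it became 16, 11 or 47. Fitted on these 6 libraries alone it was 4, and none of the 14 called genes named by rule was called. With no filter 7 of them were lost, namely Nppa, Actn2, Myl4, Plac8, Aqp1, Ly6a and Grem1. With a pseudocount of 0.1, 3 were lost, namely Nppa, Myl4 and Aqp1. Each of those 14 was lost without at least 1 library, with adjusted p up to 0.18. Myh6 was lost without untreated replicate 3, Fxyd1 without untreated replicate 2 or DMSO replicate 1, and Nppa, Aqp1 and the 2 Ly6 genes unless untreated replicate 1 was left out. Myl1, Plac8, Prox1 and Postn were lost unless it was that library or DMSO replicate 3, Actn2 unless it was untreated replicate 2 or DMSO replicate 1, and Myl4 in all 6. Replicate numbers paired the libraries of this day, and with the replicate block Aqp1 had adjusted p = 0.051. DMSO replicate 1 had the lowest median correlation with its group, 0.931, and without it and DMSO replicate 3 of day 21, 29 genes were called. In that setting 4 of the 14 named calls held. DMSO replicate 1 had 26990 genes above 0 TPM, against a mean of 30893 untreated. The RNA 7SK took 2.40% of TPM with DMSO and 2.01% without.

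At day 21 in GHMT cells, Myh6 and other muscle genes rose with DMSO, among them Myl1, Lmod2 and Actn2, and Saa3 and Tnnt3 fell. Myl1 went from 20.2 ± 8.71 to 286 ± 96.7 TPM (SD, n = 3), a log2 change of 3.78 ± 0.55 (SE) with adjusted p = 0.0021. Lmod2, an actin filament nucleator of the sarcomere, rose by 1.5 ± 0.18 (adjusted p = 0.00075), Actn2 by 2.30 ± 0.46 (adjusted p = 0.014), Nppa by 2.62 ± 0.66 (adjusted p = 0.038) and Nppb, the brain natriuretic peptide, by 2.37 ± 0.59 (adjusted p = 0.037). Hcn4, the pacemaker channel, went from 14.6 to 43.4 TPM (1.47 ± 0.36, adjusted p = 0.033). The acute phase protein gene Saa3 fell from 118 ± 124 to 3.34 ± 0.938 TPM (−4.25 ± 0.54, adjusted p = 0.0011) and Tnnt3, a fast skeletal troponin, from 20.5 ± 6.48 to 0.584 ± 0.415 TPM (−3.75 ± 0.45, adjusted p = 0.00075).

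Prl8a2 and Prl8a9, placental and decidual members of the prolactin family, had the 2 lowest log2 changes at day 21 by the naming rule, −4.39 ± 0.38 and −4.58 ± 0.33 (adjusted p = 4.3e-05 and 2.0e-05). Prl8a2 stood at 1.20 ± 0.744 against 49.1 ± 27.8 TPM with and without DMSO. The family holds related genes between which reads may be split, which was not tested, so both values are uncertain.

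Of 25 sarcomere genes 23 were higher at day 21, 8 called, among them Lmod2 and Myh6, and 12 up and 1 down when adjusted over the list alone (median 0.94, adjusted p = 2.5e-09, adjusted p = 0.34 with an estimated correlation). The natriuretic and cardiac secreted list had Nppa and Nppb called of 16 and 3 when adjusted over the list alone (median 0.39, adjusted p = 0.035, adjusted p = 0.67 with an estimated correlation). Calcium handling had Hcn4 called of 21, with 5 up and 1 down when adjusted over the list alone (median 0.25, adjusted p = 0.018, adjusted p = 0.67 with an estimated correlation). Interferon response genes were lower in 31 of 32, with 5 called, including the regulator Irf7 (−1.84 ± 0.33, adjusted p = 0.0086) and the nucleic acid sensor Zbp1 (−2.81 ± 0.54), and 17 when adjusted over the list alone (median −1.0, adjusted p = 5.5e-09, adjusted p = 0.67 with an estimated correlation). Without DMSO replicate 1 of this day 27 were called lower, with a median of −1.53. Of 25 inflammatory genes 6 fell, including Saa3 and Il6 (−1.74 ± 0.33), with 1 up and 12 down when adjusted over the list alone (median −0.89, adjusted p = 0.00022, adjusted p = 0.34 with an estimated correlation). In the Wnt list the receptor partner Lgr5 (−1.47 ± 0.25) and the inhibitor Sfrp1 (−1.60 ± 0.29) were among 6 of 20 that fell, and Wnt11 rose (1.33 ± 0.35). The list had 3 up and 9 down when adjusted over the list alone (median −0.64, adjusted p = 0.0075, adjusted p = 0.34 with an estimated correlation).

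Smooth muscle markers were lower in 13 of 15, with 4 called, including the pericyte gene Rgs5 (−1.19 ± 0.24) and Tpm2 (−1.33 ± 0.28), and 1 up and 9 down when adjusted over the list alone (median −0.82, adjusted p = 0.0013, adjusted p = 0.34 with an estimated correlation). Myofibroblast genes had 5 of 25 that fell, including Postn (−1.91 ± 0.26, adjusted p = 0.0016) and Cilp (−1.41 ± 0.19), and 6 when adjusted over the list alone (median −0.37, adjusted p = 0.0075, adjusted p = 0.67 with an estimated correlation). Matrix proteases had 6 of 21 that fell, with 1 up and 8 down when adjusted over the list alone (median −0.34, adjusted p = 0.042, adjusted p = 0.67 with an estimated correlation). The collagen and matrix list did not pass (median −0.30, adjusted p = 0.068), with 4 of 31 called, including Eln (−1.98 ± 0.40), and 5 when adjusted over the list alone. Among metabolic lists, 2 of 21 fatty acid oxidation genes rose, Acads (0.85 ± 0.19) and Acaa2 (0.48 ± 0.13), with 5 when adjusted over the list alone (median 0.06, adjusted p = 0.042, adjusted p = 0.67 with an estimated correlation). Markers of other cell types went both ways, with Krt18 (−1.38 ± 0.19) and Msln (−1.09 ± 0.21) lower and Krt7 (0.91 ± 0.24) higher, and neither their epithelial list of 8 (adjusted p = 0.33) nor their mesothelial list of 14 (adjusted p = 0.77) passed.

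By limma, 333 genes rose and 614 fell at day 21 of 20618 tested, 94 and 352 of them by more than 2-fold, and after protein-coding rescaling 797 of 1394 rose. DMSO replicate 3 had the lowest median correlation with its group of all libraries, 0.913, with 21.2% of its TPM in 7SL RNA and 0.277% in mitochondrial messenger RNA. DMSO replicate 1 had the next lowest, 0.919, and was closest to an untreated library. Genes above 0 TPM numbered 30731, 28932 and 25106 in DMSO replicates 1, 2 and 3, against a mean of 30643 untreated. Whether that bears on the excess of falls was not tested. Mitochondrial ribosomal RNA took 3.38% of TPM with DMSO and 4.40% without. The count of 947 was 272 without DMSO replicate 3, 307 without it and DMSO replicate 1 of day 7, 3138 without DMSO replicate 1 of day 21, 491 without DMSO replicate 2, and 365, 426 or 339 without untreated replicate 1, 2 or 3. Without DMSO replicate 1 of day 21, 4 of the 13 lists called at this day passed by camera, namely sarcomere, interferon, inflammatory and ribosomal protein genes, and the others had adjusted p between 0.051 and 0.11. With an estimated correlation those 4 had adjusted p between 0.90 and 0.91. Without DMSO replicate 3 and DMSO replicate 1 of day 7, the calcium handling, natriuretic, matrix protease and fatty acid oxidation lists had adjusted p = 0.17, 0.16, 0.077 and 0.064. Fitted on these 6 libraries alone the count was 6, and none of the 47 called genes named by rule was called. With a pseudocount of 0.1, 8 of the 47 were lost, among them Lmod2, Nppa, Nppb and Hcn4. Without DMSO replicate 3 and DMSO replicate 1 of day 7, 24 were lost, among them Irf7, Zbp1, Il6, Nppa and Nppb. Of those 47, 18 held without any 1 library, including Myh6, Myl1, Lmod2, Saa3, Tnnt3, Plac8, Prl8a2, Postn, Cilp, Lgr5, Sfrp1, Irf7 and Krt18. Nppa and Nppb were lost unless untreated or DMSO replicate 1 was left out, Actn2 without untreated or DMSO replicate 3. Hcn4, Acads, Wnt11 and Krt7 were lost unless DMSO replicate 1 was left out, and Acaa2 in all 6. Eln was lost without untreated replicate 1 or 3 or DMSO replicate 2, Zbp1 without untreated replicate 1 or DMSO replicate 3, Il6 and Msln without DMSO replicate 3, Rgs5 without untreated replicate 1 and Tpm2 without untreated replicate 3, with adjusted p up to 0.19.

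**Figure D3:**
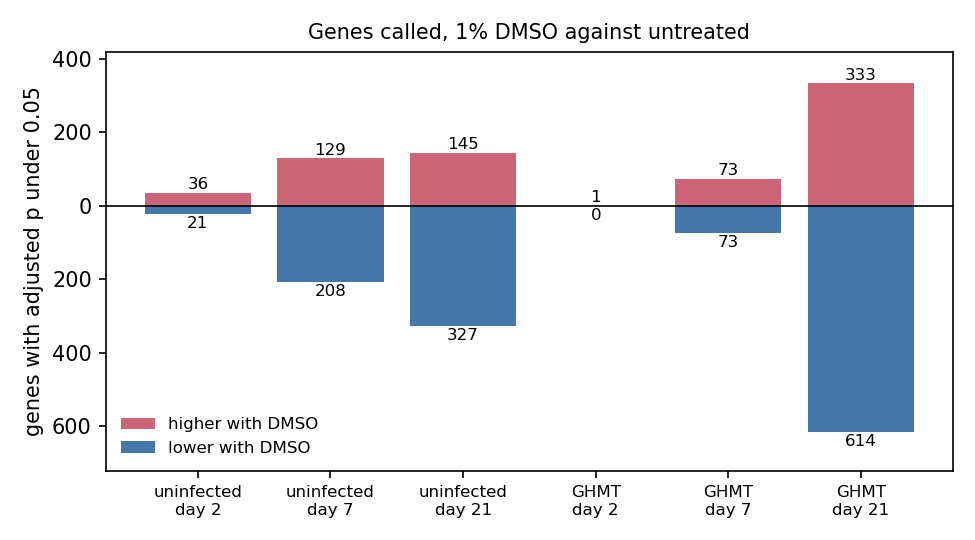
Number of genes called higher (red) and lower (blue) with 1% DMSO by limma at an adjusted p under 0.05, in each arm and at each day. The bars reach 333 higher and 614 lower genes in GHMT cells at day 21, against 1 and 0 at day 2.

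**Figure D4:**
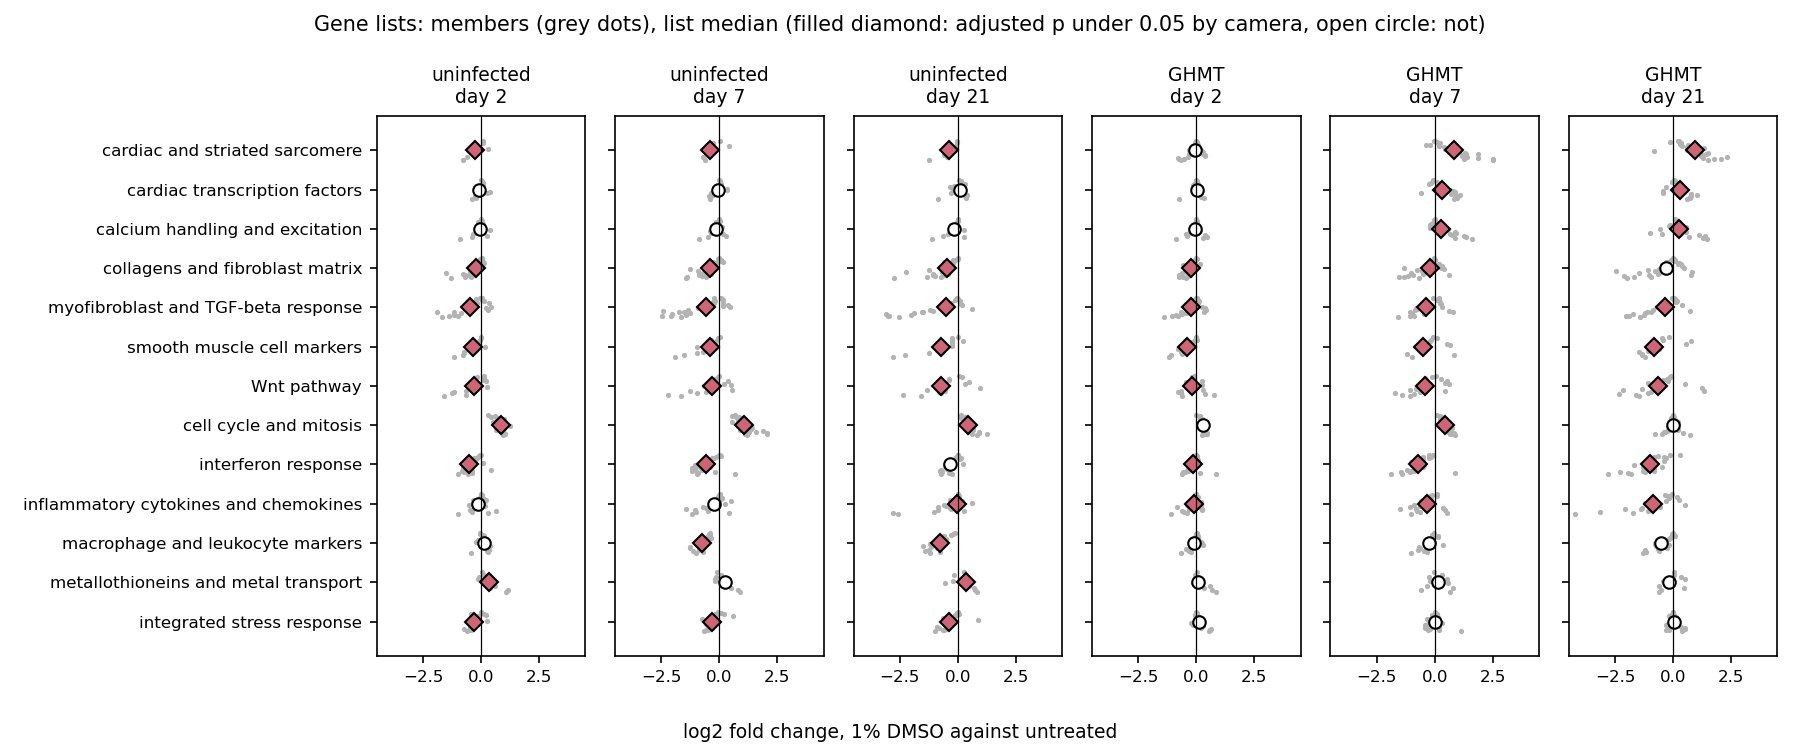
Log2 changes with 1% DMSO of the members of 13 gene lists in each arm and at each day, where grey dots are genes and larger marks are list medians, filled diamonds for lists with camera adjusted p under 0.05 and open circles for the others. The sarcomere median in GHMT cells moves from −0.04 at day 2 to 0.83 at day 7 and 0.94 at day 21.

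Whether DMSO acted differently with and without the factors was tested as the difference of the 2 effects in one fit over all 36 libraries. At day 7 the 8 sarcomere genes measured in both arms all had a higher effect in GHMT cells, by a median of 1.38 (log2), with 1 called and 6 when adjusted over the list alone. This call held with an estimated correlation (adjusted p = 3.9e-08, adjusted p = 0.020 with an estimated correlation). Actn2 differed by 3.13 ± 0.51 (SE, adjusted p = 0.033), being at 1.22 against 2.45 TPM in uninfected cells. Nrip2 (1.37 ± 0.25, adjusted p = 0.045), a nuclear receptor interacting protein, and Ufsp1 (1.31 ± 0.24, adjusted p = 0.045), a protease of the UFM1 system, differed too. So did the predicted gene Gm45123 (2.07 ± 0.37, adjusted p = 0.045), which lies outside the naming rule and was chosen after its values were seen. Replicate numbers paired the GHMT libraries of this day, and with the replicate block Nrip2 had adjusted p = 0.051 and the count of 4 genes became 7. After median ratio scaling Ufsp1 had adjusted p = 0.15. At day 21 the sarcomere list differed by a median of 1.23 with 7 of 8 members higher, 2 called and 5 when adjusted over the list alone (adjusted p = 1.3e-06 and adjusted p = 0.053 with an estimated correlation).

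At day 21 single genes differed both ways between the arms. Adamtsl2 differed by 2.5 ± 0.48 (adjusted p = 0.024), falling with DMSO from 9.95 to 0.758 TPM in uninfected cells and standing at 85.7 against 91.7 TPM in GHMT cells. The cytochrome oxidase subunit of muscle Cox6a2 differed by 2.5 ± 0.50 (adjusted p = 0.024) and Nrep by 2.40 ± 0.46 (adjusted p = 0.021). Saa3 (−3.65 ± 0.76, adjusted p = 0.033), Tnnt3 (−3.28 ± 0.55, adjusted p = 0.011) and Aqp1 (−2.66 ± 0.53, adjusted p = 0.024) had the lower effect in GHMT cells. By limma, 0 of 18796 genes differed at day 2, where 195 had an unadjusted p under 0.05, 4 at day 7, all in one direction, and 29 and 23 in the 2 directions at day 21.

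Of the differences, Tnnt3 at day 21 held without any 1 of the 12 libraries. Nrep was lost without GHMT untreated replicate 3, GHMT DMSO replicate 2 or uninfected DMSO replicate 3. Adamtsl2 was lost without GHMT untreated replicate 2, GHMT DMSO replicate 3, uninfected untreated replicate 2 or 3 or uninfected DMSO replicate 3. Aqp1 was lost without GHMT untreated replicate 1 or 2, GHMT DMSO replicate 3, uninfected untreated replicate 3 or uninfected DMSO replicate 1 or 2. Cox6a2 was lost without replicate 2 or 3 of any group except GHMT untreated replicate 2. Saa3 held without GHMT untreated replicate 2, replicate 1 of GHMT DMSO or uninfected untreated cells, or uninfected DMSO replicate 3, and was lost without any other. At day 7 Actn2 was lost, and the count of 4 became 0, without GHMT untreated replicate 3, GHMT DMSO replicate 2, uninfected untreated replicate 2 or 3 or uninfected DMSO replicate 1 or 2. That count became 2 without replicate 1 of GHMT DMSO or uninfected untreated cells or uninfected DMSO replicate 3. Ufsp1 held without GHMT untreated replicate 1 or GHMT DMSO replicate 3 and Nrip2 without GHMT untreated replicate 2, and both were lost otherwise. In these losses adjusted p went up to 0.20, and fitted on the groups of the contrast alone none of the 9 was called. Adamtsl2 was lost with a pseudocount of 5. With a pseudocount of 0.1 Saa3 and Aqp1 were lost at day 21 and Nrip2 and Ufsp1 at day 7. The count of 52 at day 21 became 29 or 19 without GHMT untreated replicate 1 or 3 and 1279, 33 or 6 without GHMT DMSO replicate 1, 2 or 3. It became 24 or 14 without uninfected untreated replicate 2 or 3 and 19 or 28 without uninfected DMSO replicate 2 or 3.

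Calls shared between the arms were counted over 18796 genes tested in both, and no control library was shared. At day 7, 4 genes rose (Dennd5b, Pop5, Rbm10 and Wdr6) and 23 fell in both arms, where independent lists would share 0.381 and 0.695. At day 21, 21 rose and 108 fell in both, where 2.18 and 8.75 would be shared. Without the 3 doubted libraries 6 rose and 81 fell in both. With all libraries 1 gene, Jade3, was called in opposite directions (0.60 in uninfected and −0.72 in GHMT cells). These 5 genes were chosen after their values were seen. Postn, Eln, Cilp, Lgr5, Mmp23 and Tpm2 were among the named genes that fell in both arms at day 21. Across genes, which are not independent replicates, the log2 changes of the arms had Pearson r = 0.26, 0.23 and 0.24 at days 2, 7 and 21. Within uninfected cells, 55 rises and 146 falls were shared by days 7 and 21 (0.936 and 3.40 for independent lists), and within GHMT cells 56 and 69 (1.18 and 2.17).

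The untreated libraries of days 2 and 21 show how each arm changed in culture. In GHMT cells, most members of the sarcomere list rose and most of the interferon and cell cycle lists fell, gene by gene. Actc1, cardiac actin, went from 0.789 ± 0.434 to 253 ± 27.7 TPM (SD, n = 3), a log2 change of 7.17 ± 0.51 (SE) with adjusted p = 2.6e-06, and Myh6 changed by 6.96 ± 0.35 (adjusted p = 1.2e-07). Of 25 sarcomere genes 20 rose, 22 when adjusted over the list alone (median 2.08, adjusted p = 7.3e-14, adjusted p = 0.33 with an estimated correlation). The antiviral effector Mx1 fell from 382 ± 64.6 to 9.24 ± 4.69 TPM (−5.33 ± 0.47, adjusted p = 8.3e-06) and the chemokine Cxcl10 from 523 ± 103 to 12.9 ± 8.46 TPM (−5.44 ± 0.54, adjusted p = 1.9e-05). Of 32 interferon genes 29 fell and 1 rose, with the same counts when adjusted over the list alone (median −2.28, adjusted p = 1.1e-27, adjusted p = 0.33 with an estimated correlation). Untreated uninfected cells of day 2 had Mx1 at 2.51 TPM and Cxcl10 at 1.41 TPM, levels from the other table and not tested. Of 30 cell cycle genes 29 fell, 30 when adjusted over the list alone (median −2.55, adjusted p = 1.7e-26, adjusted p = 0.33 with an estimated correlation).

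In uninfected cells, Hp and Cyp2f2 were among the genes that rose from day 2 to day 21, and Mdk and Plagl1 among those that fell. Haptoglobin, Hp, went from 1.77 to 48.2 TPM (4.12 ± 0.34, adjusted p = 4.9e-06) and Cyp2f2, a cytochrome P450, from 11.9 to 163 TPM (3.75 ± 0.42). The growth factor midkine, Mdk, fell from 144 to 8.13 TPM (−4.00 ± 0.18, adjusted p = 2.8e-08) and the imprinted regulator Plagl1 from 568 to 59.3 TPM (−3.27 ± 0.21). Rnu1b1 had −3.26 ± 0.37 but is 1 of several near-identical small nuclear RNA copies and is uncertain. NRF2 response genes rose in 15 of 22, 18 when adjusted over the list alone, and this call held with an estimated correlation (median 0.61, adjusted p = 3.1e-15, adjusted p = 0.045 with an estimated correlation). Cholesterol biosynthesis genes rose in 17 of 24, with 21 up and 1 down when adjusted over the list alone (median 1.19, adjusted p = 1.6e-14, adjusted p = 0.29 with an estimated correlation). Fatty acid synthesis and storage genes rose in 12 of 23, 14 when adjusted over the list alone (median 0.72, adjusted p = 8.0e-12, adjusted p = 0.29 with an estimated correlation). Cell cycle genes fell in 9 of 30, 23 when adjusted over the list alone (median −0.91, adjusted p = 2.4e-09, adjusted p = 0.41 with an estimated correlation). In that list Mki67 was higher in replicate 1 of day 21 than in the other replicates of that day.

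Over time limma called 3692 rises and 1381 falls of 20618 genes in GHMT cells and 1031 rises and 1166 falls of 19979 in uninfected cells. Median ratio scaling moved all GHMT genes by 0.29 (log2) between day 21 and day 2, and relative to that shift 2139 rose and 3245 fell. The split in uninfected cells became 1370 and 1044. The 12 genes named by rule in the 2 time contrasts, among them those above, held without any 1 library and under every other setting run. The GHMT count of 5073 became 2995 without replicate 1 of day 2 and 3372 without replicate 1 of day 21. The uninfected count of 2197 became 1367 or 1416 without replicate 2 or 3 of day 2, 1302 without replicate 3 of day 21 and 410 in a fit on the groups of the contrast alone.

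The DMSO effect of day 21 was also set against that of day 2 within each arm. In uninfected cells 1 gene differed upward and 6 downward, namely Mir669d (2.04 ± 0.22), Apoe (−2.85 ± 0.38), Postn (−2.52 ± 0.34), Dlk1 (−2.39 ± 0.34), Comp (−2.33 ± 0.24), Igf2 (−2.21 ± 0.26) and Mdk (−1.74 ± 0.25), with 797 at an unadjusted p under 0.05. Mdk had adjusted p = 0.86 with a pseudocount of 5 and 0.056 with no filter. Mir669d had adjusted p = 0.063 with a pseudocount of 0.1. Dlk1 had adjusted p = 0.056 with no filter, 0.057 on the groups of the contrast alone and 0.058 without the doubted libraries. Apoe, Postn, Comp and Igf2 were called in all of these settings. In GHMT cells Lmod2 (1.54 ± 0.26), Arr3, Nptx2, Col22a1 and Mir7682 differed upward and 9 downward, including Prl8a2 (−4.05 ± 0.54) and Prl8a9 (−4.36 ± 0.47), with 1377 at an unadjusted p under 0.05. These genes lie outside the naming rule for this contrast and were chosen after their values were seen. Replicate numbers paired the GHMT libraries of day 2, and with the replicate block 2 genes differed upward, Nptx2 and Col22a1, and 5 downward, all among the 14, while Lmod2, Arr3 and Mir7682 had adjusted p = 0.055, 0.076 and 0.062. After median ratio scaling 7 of the 14 were called, and Lmod2, Arr3, Col22a1 and Mir7682 had adjusted p between 0.056 and 0.089. With a pseudocount of 0.1, where 4 genes were called, Lmod2, Arr3 and Col22a1 had adjusted p = 0.74, 0.66 and 0.16. The uninfected count of 7 became 2 or 11 without untreated replicate 2 or 3 of day 2 and 4 without DMSO replicate 2 or 3 of day 2. The GHMT count of 14 became 6 without untreated replicate 1 or 3 or DMSO replicate 2 or 3 of day 2 and 7 without DMSO replicate 1 of day 2. It became 9, 8 or 8 without untreated replicate 1, 2 or 3 of day 21 and 33, 8 or 7 without DMSO replicate 1, 2 or 3 of day 21.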

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

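The tests of the sarcomere and matrix patterns were chosen only after the result was seen, while the regroupings of libraries and the trophoblast test were chosen before. Results stand here because the effect of DMSO differed between arms or days by a test of the difference.

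Sarcomere genes were higher with DMSO in GHMT cells, with list medians of 0.83 at day 7 and 0.94 at day 21 (adjusted p = 7.3e-07 and adjusted p = 2.5e-09, and with an estimated correlation adjusted p = 0.42 and adjusted p = 0.34). Scaling by abundant noncoding RNAs is argued against, since with libraries scaled by protein-coding genes the medians were 0.83 (adjusted p = 9.9e-07, adjusted p = 0.43 with an estimated correlation) and 1.02 (adjusted p = 3.1e-08, adjusted p = 0.48 with an estimated correlation). GHMT DMSO replicate 3 of day 21 and replicate 1 of day 7 as the source are argued against as well, with medians of 0.77 (adjusted p = 7.3e-08, adjusted p = 0.48 with an estimated correlation) and 0.84 (adjusted p = 5.3e-07, adjusted p = 0.59 with an estimated correlation) without both. Leaving out DMSO replicate 1 of day 21 (median 0.97) cannot test it, as its sarcomere mean was the lowest of its group. More transduced cells, or more of the transduced factors per cell, stays open as a candidate explanation. The mean of the 4 factors was higher by 0.91 ± 0.054 (SE over 3 pairs, all of them higher) at day 7. Unpaired, that SE was 0.36. At day 21 the factor mean was higher by 0.76 ± 0.15 (SE, unpaired). The rise of the sarcomere mean differed from that of the factors by −0.052 ± 0.173 at day 7, with an unpaired SE of 0.48, and by 0.14 ± 0.24 at day 21. Of 25 sarcomere genes, 12 at day 7 and 14 at day 21 had a larger log2 difference than the factor mean. An effect of DMSO on the cells that is separate from the factors may also hold. It cannot be called biological while the share of transduced cells and the factor levels stay open.

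Matrix, myofibroblast and smooth muscle genes were lower with DMSO in uninfected cells at day 21, with a median of −0.50 over 71 genes, 63 of them negative. Scaling is argued against, since the median was −0.47 after protein-coding scaling, and so is the 1 untreated library that stood apart, without which it was −0.46. A lower share of fibroblasts that raises all other types alike is argued against, since list medians of other cell types went from −0.76 (macrophage) to 0.46 (epicardial and mesothelial). A larger share of epicardial or mesothelial cells, with 12 of 15 markers higher, was not tested on its own and stays open. A response of the fibroblasts themselves to DMSO may also hold, and cannot be called biological while this is open.

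Prl8a2 and Prl8a9 were listed at means of 49.1 and 26.9 TPM in untreated GHMT cells at day 21. Placental trophoblast cells in the cultures are argued against as the source, since 1 of 20 other trophoblast genes, Pappa2 at 6.67 TPM, had a mean of 1 TPM or more, with a median of 0.125 TPM over the 20. The 20 did not include Prl3a1, another placental prolactin gene, which was also lower with DMSO there. The list holds trophoblast genes only, so decidual cells were not tested and stay open. Reads shared between related family members were not tested either and stay open.

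Between arms, 4 genes differed in their DMSO effect at day 7 and 52 at day 21. Actn2 (3.13), Nrip2 (1.37) and Ufsp1 (1.31) differed at day 7, where Nrip2 had adjusted p = 0.051 with the replicate block and Ufsp1 adjusted p = 0.15 after median ratio scaling. At day 21 Adamtsl2 (2.5), Cox6a2 (2.5) and Nrep (2.40) had the higher effect in GHMT cells, and Saa3 (−3.65), Tnnt3 (−3.28) and Aqp1 (−2.66) the lower. Between days 21 and 2, 7 genes differed in uninfected and 14 in GHMT cells, 7 of the latter with the replicate block.

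Gene lists differed between arms as medians of the difference with camera's test. At day 2 these were cell cycle and mitosis (−0.61, adjusted p = 8.5e-09, adjusted p = 0.99 with an estimated correlation), integrated stress response (0.40, adjusted p = 9.3e-09, adjusted p = 0.67 with an estimated correlation), unfolded protein response (−0.19, adjusted p = 5.7e-05, adjusted p = 0.67 with an estimated correlation). They were also NRF2 response (−0.14, adjusted p = 5.7e-05, adjusted p = 0.46 with an estimated correlation), Wnt pathway (0.21, adjusted p = 0.041, adjusted p = 0.67 with an estimated correlation) and cholesterol biosynthesis (0.18, adjusted p = 0.048, adjusted p = 0.99 with an estimated correlation). At day 7 they were sarcomere (1.38, adjusted p = 3.9e-08, adjusted p = 0.020 with an estimated correlation), calcium handling (0.53, adjusted p = 0.00016, adjusted p = 0.45 with an estimated correlation), cardiac transcription factors (0.62, adjusted p = 0.0015, adjusted p = 0.17 with an estimated correlation), natriuretic and cardiac secreted (0.78, adjusted p = 0.0055, adjusted p = 0.50 with an estimated correlation). Also different at day 7 were cell cycle and mitosis (−0.61, adjusted p = 1.9e-06, adjusted p = 0.87 with an estimated correlation), DNA replication (−0.28, adjusted p = 0.00015, adjusted p = 0.87 with an estimated correlation), acetyltransferase and bromodomain (0.21, adjusted p = 0.017, adjusted p = 0.87 with an estimated correlation) and ribosomal proteins (−0.13, adjusted p = 0.0057, adjusted p = 0.87 with an estimated correlation).

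At day 21 the lists that differed between arms were sarcomere (1.23, adjusted p = 1.3e-06, adjusted p = 0.053 with an estimated correlation), calcium handling (0.55, adjusted p = 0.0049, adjusted p = 0.66 with an estimated correlation), natriuretic and cardiac secreted (0.93, adjusted p = 0.0051, adjusted p = 0.66 with an estimated correlation), collagens and matrix (0.29, adjusted p = 0.026, adjusted p = 0.93 with an estimated correlation). Also different at day 21 were fatty acid oxidation (0.10, adjusted p = 0.0049, adjusted p = 0.66 with an estimated correlation), integrated stress response (0.36, adjusted p = 0.0049, adjusted p = 0.93 with an estimated correlation) and epicardial and mesothelial markers (−0.42, adjusted p = 0.0054, adjusted p = 0.83 with an estimated correlation). Of all these calls, sarcomere at day 7 held with an estimated correlation.

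Other splits of the libraries were run for each comparison. For the 3 against 3 comparisons the 10 splits are too few for a share under 0.05, so only the counts are given. The real split and the highest other called 57 and 3 genes in uninfected cells at day 2, 337 and 2 at day 7, 472 and 4 at day 21, and 1 and 14, 146 and 3, and 947 and 34 in GHMT cells at these days. Over time they called 2197 and 121 genes in uninfected and 5073 and 1 in GHMT cells. As many genes as the real split came from 1 split, the real one, in 7 of the 8 comparisons and from 4 splits in GHMT cells at day 2, where the split with 14 set untreated replicates 1 and 2 and DMSO replicate 1 against the rest. In the comparisons whose numbers pair libraries, splits that part all 3 pairs called at most 1 gene at day 2 and 3 at day 7, and the others at most 14 and 1.

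For the differences, 100 regroupings each were drawn, the real one included, but they decide nothing about chance. Where 1 of the 2 effects that are subtracted keeps its real split, the DMSO effect of that arm or day stays in the contrast, and other regroupings put it into the spread. At day 2 of the arm differences the real count of 0 is reached by all 100. As many genes as the real 4 and 52 of days 7 and 21 came from 9 and 12 regroupings, and 8 and 8 of these kept 1 effect at its real split. As many as the real 7 and 14 of the day differences came from 10 and 8, of which 8 and 5 kept 1 effect. The highest counts of 141, 771, 123 and 170 kept 1 effect too, and with both effects regrouped the highest were 2, 242, 36 and 95. At day 2 the highest, 790, had both effects regrouped, with GHMT untreated replicates 1 and 2 and DMSO replicate 1 together. The reason was not tested.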

How the results depend on the processing

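Protein-coding scaling, leaving out 3 doubted libraries, the lists of GHMT day 21 without DMSO replicate 1 and the fry test were chosen only after the result was seen. The cause of the changes below was not tested unless stated. Values were per gene, so the alternative for transcript-level values was not run. TPM keeps no depth, so what depth limits is unknown. In GHMT cells, genes above 0 TPM averaged 30882 with DMSO and 30557 without at day 2, and 29251 and 30893 at day 7. At day 21 they averaged 28256 and 30643. Whether depth lay behind these numbers could not be told.

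Counts of called genes moved by more than 1.5 times as follows. With a pseudocount of 0.1 they were 2 for GHMT day 2, 2 and 34 for the arm difference of days 7 and 21 and 4 for the day difference in GHMT cells, and with a pseudocount of 5 they were 17 for the arm difference of day 7 and 24 for that day difference. With no filter they were 52 for GHMT day 7, 29 and 170 for the arm differences of days 7 and 21 and 24 for the GHMT day difference. With a filter at 5 TPM, which tests fewer genes, they were 0 for GHMT day 2 and 0, 18 and 0 for the same 3 differences. Median ratio scaling gave 7 for the GHMT day difference. Fits on the groups of the comparison alone, with fewer libraries to estimate the spread, gave 2 and 46 in uninfected cells at days 2 and 21, 5, 4 and 6 in GHMT cells at days 2, 7 and 21. They gave 1 and 0 for the arm differences of days 2 and 21, 410 over time in uninfected cells, 11 for the uninfected day difference and 0 for the factors and reporter gene. Protein-coding scaling gave 121, 692 and 793 in uninfected cells at days 2, 7 and 21 and 5 for the factors and reporter gene. Without the doubted libraries, of which uninfected cells hold 1 and GHMT cells 2, the counts were 119, 592 and 721 in uninfected cells, 29 and 307 in GHMT cells at days 7 and 21, 2 and 15 for the arm differences of these days and 7 for the GHMT day difference. The fit without a trend moved no count by more than 1.5 times.

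With the replicate block the counts were 166, 716 and 769 in uninfected cells at days 2, 7 and 21. Same-numbered libraries correlated there at 0.09 to 0.20, 0.08 to 0.15 and 0.02 to 0.25, not all over 0.1, so pairing was not taken as given. Libraries with other numbers correlated at −0.13 to 0.06, −0.11 to −0.02 and −0.25 to 0.08, below every same-numbered pair at days 2 and 7. Pairing at those days thus stays open. The block gave 7 and 94 for the arm differences of days 7 and 21 and 15 and 7 for the day differences. In GHMT cells at day 21 same-numbered libraries correlated at 0.07 to 0.19, not all over 0.1, and the others at −0.11 to 0.01. Pairing there was not taken as given either, but stays open. Over time same-numbered libraries correlated at −0.10 to 0.10 in uninfected and −0.03 to 0.01 in GHMT cells, within the range of the others. In GHMT cells at days 2 and 7, where all same-numbered correlations were over 0.1, the block gave 1 gene at day 2 and 201 at day 7. Of the 201, 132 were among the 146, and Aqp1 was the only named call of those DMSO effects that changed. The block sets the same replicate effect on all days of an arm, so it does not model pairing within a day. In the arm difference of day 7, whose GHMT libraries are paired, it gave Nrip2 adjusted p = 0.051. In GHMT cells at day 21, where pairing was not taken as given, it gave Mef2c adjusted p = 0.038 and Krt7 0.053.

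Leaving out 1 library gave from 10 to 29, 81 to 155 and 224 to 721 called genes in uninfected cells at days 2, 7 and 21, and from 0 to 2, 11 to 111 and 272 to 3138 in GHMT cells. It gave 0 for the arm difference of day 2 whichever library was left out (195 at an unadjusted p under 0.05 by limma with all) and from 0 to 6 and 6 to 1279 for those of days 7 and 21. It gave from 1302 to 2240 and 2995 to 4532 over time, and from 2 to 11 and 6 to 33 for the day differences. The lowest and highest came without untreated replicate 3 or DMSO replicate 1 and untreated replicate 2, untreated replicate 2 and DMSO replicate 2, and DMSO replicate 3 and untreated replicate 1 in uninfected cells. In GHMT cells they came without DMSO replicate 2 or 3 and untreated replicate 1, untreated replicate 2 or DMSO replicate 2 and untreated replicate 1, and DMSO replicates 3 and 1.

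Of the list calls, 3 of 137 held with an estimated correlation and 52 by fry, which called 68 lists in all, and 12 were lost with median ratio scaling, 4 with the replicate block, 3 with protein-coding scaling, 1 with a pseudocount of 0.1 and 21 without the doubted libraries. Without untreated replicate 1 of day 21, the inflammatory list in uninfected cells at that day turned from −0.05 to −0.11 by median with a test in the other direction (adjusted p = 0.94). Of 190 values of named genes, called or not, those with the same direction and the same side of the threshold numbered 168 with a pseudocount of 0.1, 183 with 5, 155 with no filter, and 175 with median ratio scaling. They numbered 186 with the replicate block, 69 in fits on the groups of the comparison alone, 181 without the trend and 183 with protein-coding scaling. The filter at 5 TPM kept all 159 that had a value, and 144 of 189 were kept without the doubted libraries. Leaving out 1 library kept 756 of 1188.

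Values that changed sign were all of genes not called. Hand2 turned from −0.049 to 0.014 in uninfected cells at day 2 without untreated replicate 1 (lowest −0.092, without untreated replicate 3), from 0.02 at day 7 to −0.17 without untreated replicate 3, −0.07 without DMSO replicate 1 and −0.02 without DMSO replicate 2 (highest 0.17, without untreated replicate 1), and from 0.11 in GHMT cells at day 2 to −0.065 without untreated replicate 2. Gata4 in uninfected cells at day 7 turned from −0.0023 to 0.00894 with a pseudocount of 0.1, 0.018 with median ratio and 0.023 with protein-coding scaling, and 0.13, 0.03 and 0.09 without untreated replicates 2 and 3 and DMSO replicate 1. Tbx5 turned from −0.17 to 0.056 in uninfected cells at day 21 without untreated replicate 2 (lowest −0.43, without untreated replicate 1). Mef2c in GHMT cells at day 2 turned from 0.07 to −0.02, −0.051 and −0.03 without untreated replicates 2 and 3 and DMSO replicate 1 (highest 0.29, without untreated replicate 1).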

Other observations

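Genes named in this part were chosen after their values were seen, and the 2 tests of imprinted genes were chosen before their result was seen.

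In untreated uninfected cells the lipid droplet coat gene Plin1 rose by 3.35 ± 0.54 between days 2 and 21 on the log2 scale (SE, n = 3 and 3), and the fatty acid binding protein Fabp4 by 2.96 ± 0.54. The adipokine Adipoq rose by 2.92 ± 0.57 and the fatty acid transporter Cd36 by 2.74 ± 0.50 (limma, adjusted p = 0.0012, 0.0032, 0.0049 and 0.0032). Of 21 p53 targets 9 rose, and 10 when adjusted over the list alone (median 0.61, adjusted p = 1.9e-07, adjusted p = 0.29 with an estimated correlation). Of 25 immediate early genes 6 rose, with 12 up and 1 down when adjusted over the list alone (median 0.81, adjusted p = 2.8e-07, adjusted p = 0.36 with an estimated correlation). Of 33 oxidative phosphorylation genes 11 rose, and 14 when adjusted over the list alone (median 0.24, adjusted p = 3.2e-08, adjusted p = 0.29 with an estimated correlation). Ribosomal protein genes fell in 10 of 32, and in 21 when adjusted over the list alone (median −0.35, adjusted p = 2.2e-08, adjusted p = 0.41 with an estimated correlation). In untreated GHMT cells, natriuretic and cardiac secreted genes rose in 11 of 16, and in 13 when adjusted over the list alone (median 1.59, adjusted p = 7.1e-06, adjusted p = 0.33 with an estimated correlation). Calcium handling genes rose in 12 of 21, and in 13 when adjusted over the list alone (median 1.02, adjusted p = 3.4e-05, adjusted p = 0.37 with an estimated correlation). Myofibroblast genes rose in 12 of 25, with 13 up and 1 down when adjusted over the list alone (median 0.99, adjusted p = 0.0030, adjusted p = 0.37 with an estimated correlation). In the same cells DNA replication genes fell in 21 of 29 and rose in 1, against 24 and 1 when adjusted over the list alone (median −0.95, adjusted p = 5.4e-16, adjusted p = 0.33 with an estimated correlation).

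Igf2, Dlk1 and H19, which are imprinted, fell with DMSO in uninfected cells at day 21. The growth factor gene Igf2 stood at 57.6 ± 9.21 against 352 ± 70.8 TPM (SD, n = 3; −2.59 ± 0.19, adjusted p = 6.1e-06), Dlk1 changed by −2.51 ± 0.24 and H19 by −2.39 ± 0.32, while Meg3 (−0.13), Mest (−0.33) and Plagl1 (0.26) were not called. Over time in untreated uninfected cells Igf2 changed by −2.77 ± 0.19, Mest by −2.38 ± 0.28, Dlk1 by −2.21 ± 0.24 and Meg3 by −1.95 ± 0.20. The hypothesis that imprinted genes as a class are lower was tested on a list of 23 others. Over time its median was −0.65 with 13 that fell and 0 that rose (camera p = 2.9e-09, and p = 0.0021 with an estimated correlation), which is consistent with the hypothesis. With DMSO at day 21 its median was −0.12 and no member was called (p = 0.125, and p = 0.331 with an estimated correlation). A p of 0.05 or more had been set in advance to count against the hypothesis, but a test that does not pass cannot show that the class was not lower, so it stays open there, a reading made after the result was seen.

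Prl3a1, another placental prolactin gene, had a change of −2.82 ± 0.45 in GHMT cells at day 21 and belongs to the same family of related genes. Mki67, a marker of cycling cells, stood at 4.02 TPM in uninfected untreated replicate 1 of day 21 and at 0.49 and 0.25 TPM in replicates 2 and 3.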
